A study of Mus musculus with 20 samples.

How the data were processed

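The series holds 20 RNA libraries from mouse colon in 5 groups of 4 animals. On chow these are floxed littermates without Cre (ff), animals lacking Pcca in the intestinal epithelium through Villin-Cre (Vill), and animals lacking Pcca in the liver through Albumin-Cre (Alb). On a high fat diet (HFD) the groups are ff and Vill. Chow animals were killed at 9 weeks. HFD animals ate a diet with 60% of its energy from fat for 12 weeks and were 18 weeks old. Colons were flushed, frozen and extracted whole, and libraries were made from poly-A RNA.

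Per the file headers, the deposited tables hold read counts per gene and library, with 28 further per-sample columns (FPKM and normalized values) that were not used. The authors' deposited tables also give a log2 fold change and a p-value with an adjusted p-value for each comparison, which were read only to be set beside the new tests. The chow tables list 56748 genes, of which 22157 have no read in any chow library, and the HFD table lists 31184 genes, all of which are in the chow tables. Genes were matched by their Ensembl identifiers, because 2693 genes of the chow tables have no symbol of their own. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0, edgeR 3.22.5 and the mm39 genome. They do not say which of DESeq2 and edgeR made which column, nor which annotation release was used, nor settle whether the libraries keep the strand. Coordinates below are those of the deposited tables.

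Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, default expression filter) under R 4.3.3. The 3 chow comparisons came from a single fit of 12 libraries, the HFD comparison from a fit of 8, and the difference between diets from a fit of the 16 ff and Vill libraries. Tested were 19701 genes on chow, 17715 on HFD and 19516 across diets. P-values were adjusted by Benjamini and Hochberg over all tested genes, and a gene was called at an adjusted p under 0.05. Ranges in brackets after a log2 fold change are 95% intervals. CPM are library-size-scaled counts on the TMM scale, given as mean ± SD over 4 animals. Values of single libraries, and the Pcca means beside them, were scaled before the expression filter and the other means after it. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run on the same counts. Single values of 2 groups of 4 were also compared by an exact permutation test over all 70 assignments, whose smallest possible 2-sided p is 0.0286.

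Gene lists were written from general knowledge: 19 pathway lists and 22 cell type lists, of which 20 cell type lists had enough measured members. Each was tested with camera on the edgeR counts and their fitted spread, with the preset correlation of 0.01. Each was then tested again with the correlation estimated from the libraries, and adjusted within its kind of list. Within a list, member p-values were also adjusted over the list alone. Named genes follow a fixed rule: Pcca and passing members of the propionate list, then the called genes with the largest fold changes at a mean of 2 CPM or more, then the 10 smallest p-values where fewer genes were called, then leading members of the lists, and the genes Vil1 and Alb whose promoters drive the Cre lines.

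The comparisons, the tests, the lists, the rule for naming genes and most alternatives were fixed before the data were examined. Chosen after seeing the data were the average of the Vill effect over both diets, a fit with colon position as a covariate, the fit without HFD ff 1 and 3, the permutation of list means, and the carry-over without the chromosome 8 genes near Gm45774. The carry-over from chow to HFD was planned on the called genes, of which there was 1, and uses the 200 genes with the smallest chow p instead. Alternatives with a called set at other limits, or with a pseudocount on deposited values, were not run because there was nothing to apply them to. Surrogate variables came from sva 3.50.0. Some members of the lists are not reported here.

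The power of the tests was measured on simulated counts, drawn from the mean and fitted spread of each gene. Genes were drawn independently of each other, so structure shared by the real libraries is missing from these counts. On chow, Vill against ff, 5.97%, 38.8% and 80.3% of genes altered 1.5-fold, 2-fold and 4-fold were recovered among 19219 genes. The same shares were 5.97%, 56.7% and 83.3% for Alb against ff (19299 genes), and 7.46%, 40.3% and 83.3% for Vill against Alb (19250 genes). On HFD they were 2.99%, 32.8% and 87.9% of altered genes among 17345. For the difference between diets they were 2.99%, 19.4% and 68.2% (19082 genes), and for the average over diets 40.3%, 68.7% and 97% (19159 genes). Of the calls made in these simulations 2.35%, 3%, 3.33%, 10.9%, 7.69% and 4.2% were false, in the same order. The shares above the nominal 5% rest on 10 false calls for HFD and 5 for the difference between diets. With 1 list of 39 shifted in simulated counts, the list test called 1 list, the shifted one. Members of a list did not vary together in these counts, so this does not test the preset correlation.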

Results

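All 12 chow libraries carry Xist at 22486 to 59322 reads and no Ddx3y read, the pattern of females, whereas all 8 HFD libraries carry Ddx3y at 1458 to 2756 reads and at most 12 Xist reads, the pattern of males. Diet, age and sex therefore differ together between the chow and HFD libraries. Chow libraries hold 27.9 to 40.4 M counted reads and HFD libraries 16.9 to 24.4 M. Mitochondrial transcripts make up 3.14 to 4.07% of chow reads and 4.5 to 9.75% of HFD reads. Ribosomal RNA genes take 1.83 to 2.14% of reads in HFD Vill and 1.4 to 1.82% in HFD ff. Every HFD Vill library thus lies above every HFD ff library, and no test was adjusted for that share. Within chow, ff libraries hold 33.6 to 35.8 M reads, Vill 27.9 to 40.4 M and Alb 27.9 to 38 M. Within HFD, ff libraries hold 16.9 to 24.4 M and Vill 18.5 to 24.2 M. The first 2 principal components take 40.3% and 11.7% of the variance on chow, and 48.6% and 15.1% on HFD.

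Pcca encodes the alpha subunit of propionyl-CoA carboxylase, the mitochondrial enzyme that carries propionate carbon towards the citric acid cycle. Villin-Cre acts in the epithelium only, and the colon was extracted whole, so transcripts from muscle, stroma and immune cells remain in the count. Which part of Pcca is deleted is not stated in the deposited records, and a count over the gene (ENSMUSG00000041650, chromosome 14, 122771736 to 123128512) also takes reads from outside that part. In chow ff animals Pcca stood at 54.2, 39.4, 57.5 and 40.9 CPM, in chow Vill animals at 27.9, 33.7, 29.2 and 29.4, and in chow Alb animals at 58.0, 39.0, 40.6 and 43.4. On HFD, ff animals had 29.6, 54.1, 32.2 and 59.4 CPM and Vill animals 33.8, 36.8, 33 and 34.4. Every chow Vill animal lay below every chow ff animal, with a log2 difference of -0.67 (-1.02 to -0.33), leaving 62.6% of the ff level. This difference passed the test adjusted over the list alone (adjusted p = 0.032), the list being the propionate pathway, and not over all genes (adjusted p = 1). By exact permutation it reached p = 0.0286. In Alb colons Pcca was at 94.3% of ff (log2 -0.08, adjusted p = 0.99, exact permutation p = 0.8). On HFD the log2 difference was -0.35 (-0.85 to 0.16, adjusted p = 0.932, exact permutation p = 0.429), with 34.5 ± 1.64 CPM in Vill and 43.8 ± 15.1 in ff. HFD ff 1 and 3 lay below every Vill animal and are the libraries with small intestine genes described below. The other ff animals, at 54.1 and 59.4 CPM, lay above every Vill animal. Pccb, which encodes the beta subunit, showed a mean log2 difference of 0.13 on chow (exact permutation p = 0.6).

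**Figure D1:**
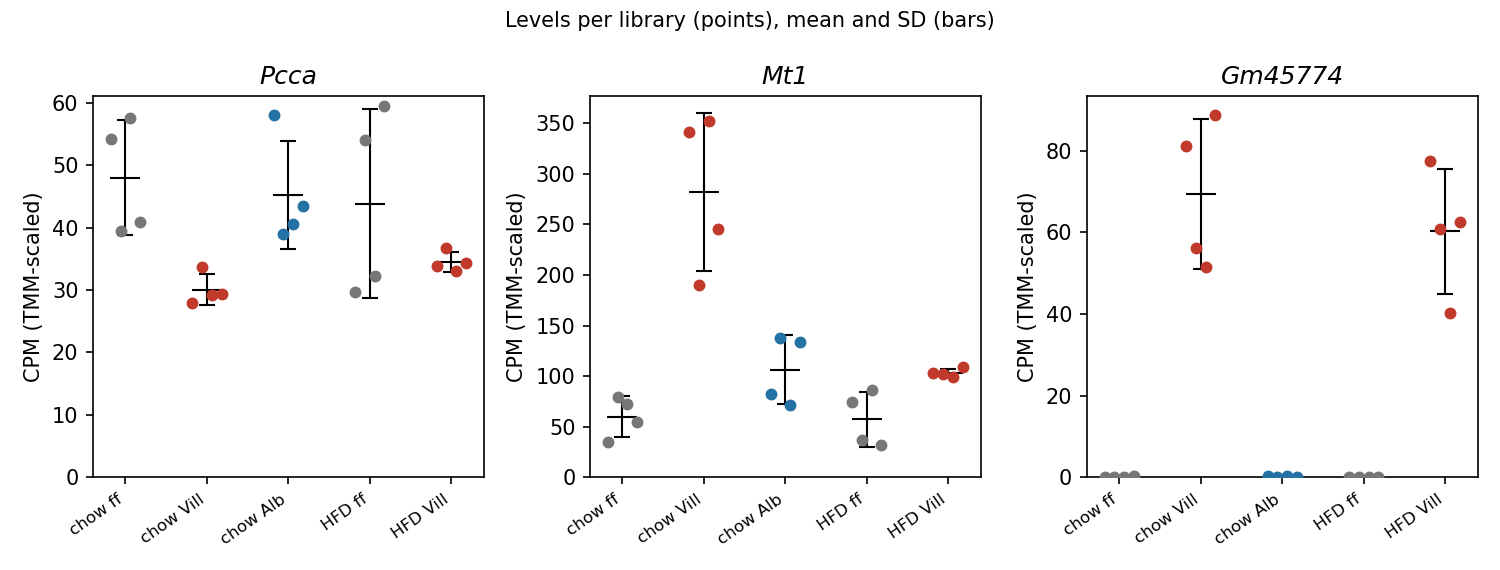
Pcca, Mt1 and Gm45774 in each library, with mean and SD per group. The Gm45774 signal is confined to the 2 Vill groups.

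Deleting Pcca in the intestinal epithelium removes propionyl-CoA carboxylase from the cells that take up the short-chain fatty acids made by colonic bacteria. Colonocytes also oxidise fatty acids and amino acids that yield propionyl-CoA. The comparison of chow Vill with chow ff asks which transcripts of the whole colon follow that loss. The median standard error of a log2 fold change was 0.26.

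With edgeR 1 of 19701 genes was called, and 374 had an unadjusted p under 0.05 where 985 would be expected without any difference. DESeq2 called 4 genes (Gm45774, Mt1, Ciapin1, Igkv14-130) and limma-voom 1. The called gene is Gm45774 (ENSMUSG00000110588, chromosome 8, 94897376 to 94900040, minus strand), a long non-coding RNA without a described function. It rose from 0.152 ± 0.172 to 69.3 ± 18.6 CPM (log2 8.78, SE 0.73, adjusted p = 0.00114), on 21 reads in ff and 9318 in Vill, a ratio of 435 (284 to 703, counting error only, without the spread between animals). Gm45774 overlaps Mt2 (94899292 to 94900196) on the opposite strand, so reads from the shared stretch cannot be placed for certain while the strand protocol is unsettled. Mt2 itself was counted at 0.818 ± 0.288 CPM in Vill and 0.259 ± 0.137 in ff (log2 1.66, adjusted p = 1). These counts rest on 120 and 35 reads and share that limit, so they may not give the level of Mt2. The metallothioneins bind zinc and copper, and Mt1 (94905710 to 94906955) stood at 282 ± 77.2 CPM in Vill against 60.0 ± 20.0 in ff (log2 2.23, SE 0.31, adjusted p = 0.121, exact permutation p = 0.0286). Ciapin1, which encodes an iron-sulfur cluster assembly factor and lies within 1 Mb, was at 42.2 ± 2.55 against 30.8 ± 1.70 CPM (log2 0.46, adjusted p = 0.738). Mt4, a metallothionein of stratified epithelia, differed by a log2 of 4.17 at 1.40 against 0.0748 CPM (adjusted p = 1).

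The other genes with the smallest p-values were not called and lay mostly lower in Vill, each with adjusted p = 1. P2rx7, an ATP-gated ion channel of immune and epithelial cells, had 9.47 ± 1.10 against 14.6 ± 1.51 CPM (log2 -0.62). Serpinb9, a granzyme B inhibitor, had 8.42 ± 1.10 against 12.7 ± 1.15 CPM (log2 -0.60). Cpa6, a carboxypeptidase, differed by -1.71, Epor, the erythropoietin receptor, by -1.86, the non-coding 5830444B04Rik by -1.18 and the pseudogene Gm6365 by -1.63. Vil1, whose promoter drives Cre in these animals, was level at 920 ± 239 and 931 ± 275 CPM (log2 -0.02). Alb, the albumin gene, had 19.7 ± 21.7 CPM in Vill and 1.53 ± 1.32 in ff (log2 3.68, adjusted p = 1), with most of it in Vill 1 and 4.

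The authors' deposited table calls 7 genes here, 4 higher and 3 lower. The authors' deposited table gives Gm45774 a log2 of 8.82, Mt1 2.22 (adjusted p = 2.33e-09), Mt4 4.23 and Cyp2w1 1.79, and lists Cx3cl1 at -0.52, 5830444B04Rik at -1.18 and Igkv14-130 at -7.15. Pcca is at -0.68 with an adjusted p of 0.16 in the authors' deposited table.

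Several lists passed with the preset correlation, none with an estimated one. Over the 35 splits of these 8 libraries into groups of 4, leaving out the real one, a median of 7 pathway lists passed with the preset correlation. The propionate list leaned upwards although it includes Pcca, with 26 of 30 measured members higher (median log2 0.09, adjusted p = 0.0355, adjusted p = 0.826 with an estimated correlation). Fatty acid oxidation had 22 of 27 members higher (median log2 0.19, adjusted p = 0.0013, adjusted p = 0.826 with an estimated correlation), and cell division 21 of 22 (median log2 0.14, adjusted p = 0.033, adjusted p = 0.826 with an estimated correlation). The unfolded protein response had 17 of 18 members lower (median log2 -0.21, adjusted p = 0.00298, adjusted p = 0.826 with an estimated correlation). All 7 MHC class II genes, which serve antigen presentation, were lower (median log2 -0.51, adjusted p = 0.00148, adjusted p = 0.826 with an estimated correlation).

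Among cell types the smooth muscle markers were lower for 10 of 10 members (median log2 -0.51, adjusted p = 1.49e-05, adjusted p = 0.596 with an estimated correlation). Fibroblast markers were lower for 9 of 9 (median log2 -0.37, adjusted p = 5.7e-05, adjusted p = 0.473 with an estimated correlation), neurons and glia for 12 of 13 (median log2 -0.27, adjusted p = 0.00396, adjusted p = 0.596 with an estimated correlation), and macrophages for 8 of 9 (median log2 -0.29, adjusted p = 0.00976, adjusted p = 0.596 with an estimated correlation). Goblet cell (median log2 -0.24), endothelial (-0.21) and skeletal muscle (-0.52) markers leaned the same way, with adjusted p of 0.0122, 0.0254 and 0.0134, and adjusted p = 0.596, 0.596 and 0.473 with an estimated correlation. Red blood cell genes were higher for 4 of 4 (median log2 0.73, adjusted p = 0.0122, adjusted p = 0.596 with an estimated correlation).

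**Figure D2:**
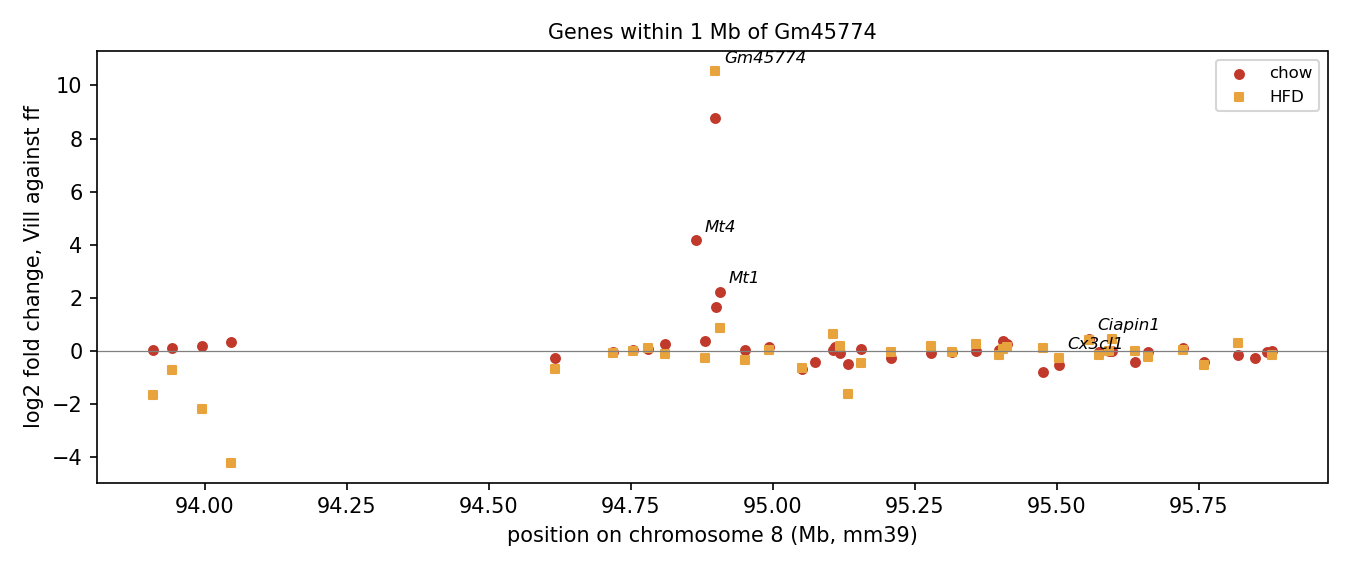
Log2 fold changes of Vill against ff for the genes within 1 Mb of Gm45774 on chromosome 8, on chow and on HFD.

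Animals without Pcca in the liver keep the enzyme in the gut, so their colons meet only the systemic consequences of the loss. The liver handles most propionate that reaches the portal vein, and propionyl-CoA derivatives in blood rise when it cannot. Their colons were compared with those of the same ff animals used above.

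No gene was called with edgeR (0 of 19701), with 867 at an unadjusted p under 0.05 against 985 expected. DESeq2 called 4 (Hsd17b12, Idi1, Cirbp, Ccdc66) and limma-voom 0. The smallest p-values include Idi1, an isomerase of isoprenoid synthesis, at 30.1 ± 4.49 CPM in Alb against 57.4 ± 7.47 in ff (log2 -0.93, SE 0.16, adjusted p = 0.855). Hsd17b12, which elongates fatty acids and reduces steroids, was at 76.9 ± 6.78 against 105 ± 3.45 CPM (log2 -0.45, adjusted p = 0.855). Cirbp, a cold-inducible RNA-binding protein, was at 52.1 ± 4.86 against 30.8 ± 3.02 CPM (log2 0.75, adjusted p = 0.891). Glyceraldehyde-3-phosphate dehydrogenase (Gapdh) had 16.0 ± 0.96 against 24.6 ± 4.06 CPM (log2 -0.62). Ldah, a lipid droplet hydrolase (-0.37), Cd101, a leukocyte surface protein (-1.78), and the transcription factor Foxn3 (0.50) share the adjusted p of 0.891. Ccdc66, a ciliary protein, differed by 0.60, Fgfr2, a fibroblast growth factor receptor, by 0.47, and Ocrl, an inositol phosphatase, by 0.36 (adjusted p = 0.983, 0.99 and 0.99). Vil1 differed by -0.19 and Alb by 1.63, neither called. Mt1 differed by 0.83 (adjusted p = 0.99), and Gm45774 was as low as in ff at 0.128 ± 0.122 CPM. The authors' deposited table calls 5 genes, 2 higher and 3 lower, among them Cirbp (0.76) and Idi1 (-0.92).

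Cholesterol synthesis and uptake was the list with the strongest difference. All 22 members were lower in Alb (median log2 -0.57, adjusted p = 5.47e-26, adjusted p = 0.173 with an estimated correlation). The mean of the list was 5.76 ± 0.22 in Alb and 6.35 ± 0.26 in ff on the log2 scale (exact permutation p = 0.0286). With p-values adjusted over the list alone 12 members passed, against 0 over all genes. They include Idi1 (adjusted p = 0.00191), Msmo1, a sterol oxidase (log2 -0.74, adjusted p = 0.0104), Cyp51, the lanosterol demethylase (log2 -0.97, adjusted p = 0.0227), Mvd, the mevalonate decarboxylase (log2 -0.77, adjusted p = 0.0227), and Hmgcs1, its HMG-CoA synthase (log2 -0.86, adjusted p = 0.0394).

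Cell division was lower for 22 of 22 members (median log2 -0.62, adjusted p = 9.67e-13, adjusted p = 0.479 with an estimated correlation), led by Ube2c (-0.91), Cdc20 (-0.84) and Mki67 (-0.68). The unfolded protein response was lower for 17 of 18 (median log2 -0.37, adjusted p = 2.51e-08, adjusted p = 0.479 with an estimated correlation). Oxidative phosphorylation (median log2 -0.09, adjusted p = 0.0116, adjusted p = 0.88 with an estimated correlation) and interferon response (median log2 -0.22, adjusted p = 0.0476, adjusted p = 0.88 with an estimated correlation) were also lower. Circadian genes were higher for 17 of 19 (median log2 0.40, adjusted p = 0.0417, adjusted p = 0.807 with an estimated correlation), among them the repressor Cry2 (0.87).

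B and plasma cell genes were lower for 11 of 11 members (median log2 -0.82, adjusted p = 0.0042, adjusted p = 0.854 with an estimated correlation) and goblet cell genes for 10 of 10 (median log2 -0.32, adjusted p = 0.00378, adjusted p = 0.854 with an estimated correlation). Neuron and glia markers were higher for 11 of 13 (median log2 0.51, adjusted p = 0.0042, adjusted p = 0.854 with an estimated correlation). The keratins Krt5 (5.49) and Krt14 (3.08) of squamous epithelium passed when adjusted over the list alone (adjusted p = 0.0143), against 0 over all genes. That difference rests on Alb 2, whose squamous list mean was 2.34 while every other library of the comparison lay at -2.03 or lower.

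**Figure D3:**
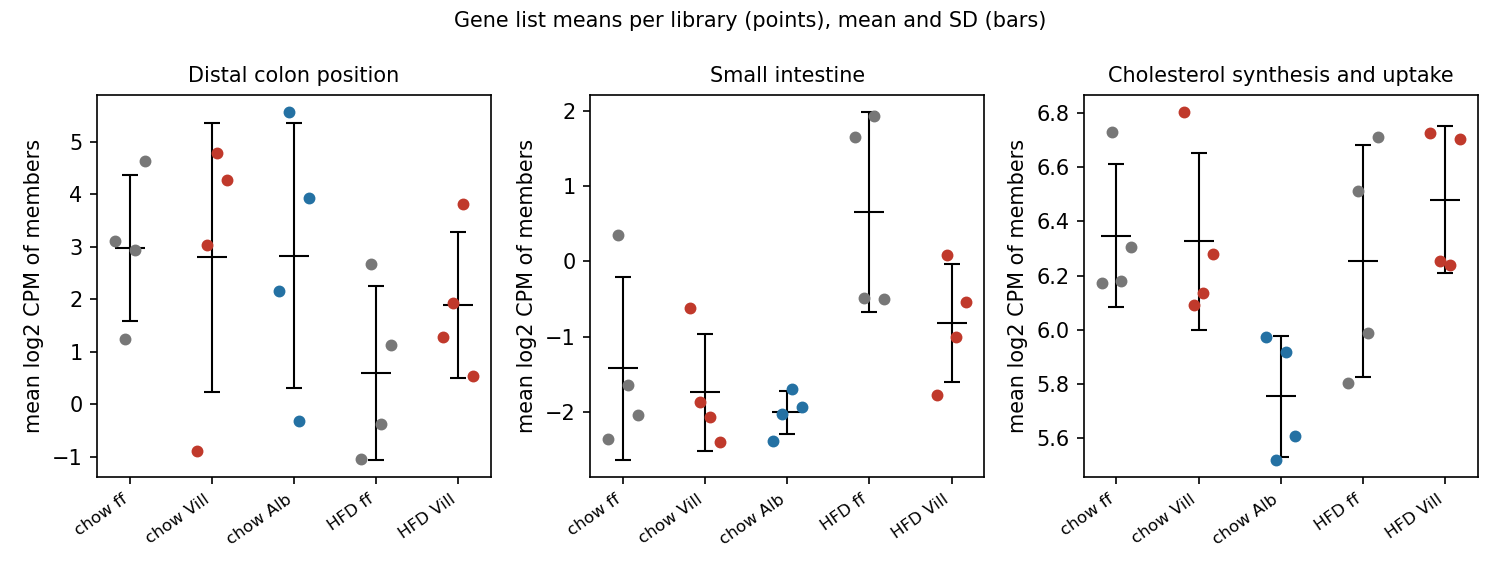
Mean log2 CPM of the distal colon position, small intestine and cholesterol lists in each library, with mean and SD per group.

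Setting the 2 knockouts against each other compares loss of Pcca in the gut with loss in the liver. The groups carry different Cre lines, so the contrast also holds any effect of the transgenes. Neither group shares animals with the other.

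With edgeR 1 of 19701 genes was called and 1748 had an unadjusted p under 0.05, against 985 expected. Gm45774 rose in Vill over Alb (log2 9.12, SE 0.75, adjusted p = 0.00105). DESeq2 called 65 genes, 22 higher and 43 lower in Vill, limma-voom called 1, and the authors' deposited table calls 67 (28 higher, 39 lower). Pcca had a log2 difference of -0.60 (adjusted p = 0.46, exact permutation p = 0.0286). Not called but next in p were Tfpi, an inhibitor of tissue factor, at 7.63 ± 1.15 CPM in Vill against 14.6 ± 1.53 in Alb (log2 -0.93, SE 0.14, adjusted p = 0.238), and a group at adjusted p = 0.246. That group holds the mucin-type glycosyltransferase Galnt15 (-1.39), the smooth muscle microRNA gene Mir143 (-2.84), Fgfr2 (-0.58), the lipid phosphatase Plpp3 (-0.68), Nynrin (-0.92), Ciapin1 (0.46) and Gapdh (0.68). Cpa6 stood at -2.03 (adjusted p = 0.292).

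Several lists differed in the direction opposite to Alb against ff, a contrast that holds the same Alb animals with the other sign. Cholesterol synthesis and uptake was higher in Vill for 22 of 22 members (median log2 0.59, adjusted p = 1.55e-17, adjusted p = 0.253 with an estimated correlation), and its mean differed with an exact permutation p of 0.0286. Adjusted over the list alone 13 members passed, Idi1 first (log2 0.79, adjusted p = 0.00786). Cell division was higher for 22 of 22 (median log2 0.71, adjusted p = 5.69e-15, adjusted p = 0.253 with an estimated correlation), with 10 members passing when adjusted over the list alone, Mki67 (0.84), Cdc20 (0.97), Ube2c (1.01) and Ccnb2 (0.76) among them. Over all genes no member of either list passed. Fatty acid synthesis (median log2 0.26, adjusted p = 0.0374, adjusted p = 0.253 with an estimated correlation) was led by the synthase Fasn (0.74). Oxidative phosphorylation was higher for 30 of 30 (median log2 0.14, adjusted p = 0.000602, adjusted p = 0.823 with an estimated correlation). The integrated stress response (median log2 0.26, adjusted p = 0.0212, adjusted p = 0.823 with an estimated correlation) and the unfolded protein response (median log2 0.14, adjusted p = 0.0401, adjusted p = 0.838 with an estimated correlation) were higher as well.

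Circadian genes were lower in Vill for 16 of 19 (median log2 -0.57, adjusted p = 0.00532, adjusted p = 0.624 with an estimated correlation), with Cry2 (-1.11) passing when adjusted over the list alone (adjusted p = 0.013), against 0 over all genes. MHC class II was lower for 7 of 7 (median log2 -0.56, adjusted p = 0.00532, adjusted p = 0.823 with an estimated correlation). Neuron and glia markers (median log2 -0.90, adjusted p = 1.58e-06, adjusted p = 0.526 with an estimated correlation) and smooth muscle markers (median log2 -0.86, adjusted p = 7.41e-07, adjusted p = 0.526 with an estimated correlation) were lower, as were fibroblast markers (median log2 -0.48, adjusted p = 0.000519, adjusted p = 0.526 with an estimated correlation) and endothelial markers (median log2 -0.34, adjusted p = 0.0114, adjusted p = 0.542 with an estimated correlation). Red blood cell genes were higher for 4 of 4 (median log2 0.84, adjusted p = 0.0114, adjusted p = 0.526 with an estimated correlation).

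The Alb and Vill contrasts share the ff animals, which by itself makes their fold changes correlate. The observed correlation of the 2 sets of fold changes was 0.252, with 54.5% of genes on the same side, below the 0.5 and 66.7% that shared controls alone gave in simulation. Genes varied independently in that simulation, so the gap cannot be read as opposed effects of the 2 knockouts.

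A high fat diet loads the gut with long-chain fat and changes the bacteria that make propionate. HFD Vill was compared with HFD ff after 12 weeks of that diet, a comparison in which lower Pcca was not established (exact permutation p = 0.429). The ff animals with the lowest Pcca, HFD ff 1 and 3, are the libraries with small intestine genes described below. The median standard error was 0.23.

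With edgeR 1 of 17715 genes was called, and 612 had an unadjusted p under 0.05 against 886 expected. DESeq2 called 4 (Gm45774, Rn18s-rs5, Osr2, Ggt1) and limma-voom 1. Gm45774 rose from 0.0372 ± 0.0256 to 60.3 ± 15.4 CPM (log2 10.54, SE 0.40, adjusted p = 2.07e-05), on 3 reads in ff and 4880 in Vill, a ratio of 1670 (570 to 8090, counting error only, without the spread between animals). Mt1 differed by 0.84 (103 ± 2.73 against 57.7 ± 27.5 CPM) and Ciapin1 by 0.41, both with adjusted p = 0.932 and not called. The same adjusted p belongs to the genes next in rank. Apoe, a lipid carrier of macrophages, was at 84.4 ± 6.39 against 111 ± 6.46 CPM (log2 -0.39), and Cyba, a subunit of NADPH oxidases, at 33.7 against 44.3 CPM (log2 -0.39). Tmem37, a calcium channel subunit, stood at 17.3 against 9.12 CPM (log2 0.92), the ribosomal protein pseudogene Gm8730 at 13.8 ± 3.92 against 6.87 ± 0.525 CPM (log2 1.00), and Phrf1, a ubiquitin ligase, at 70.7 against 56.6 CPM (log2 0.32). Bglap3 (-1.13), the histone gene H1f3 (1.04) and the GABA receptor gene Gabrb1 (-1.90) complete the group. Vil1 differed by 0.22 and Alb by -0.73. Ggt1, which degrades glutathione at the cell surface, had 0.595 ± 0.209 CPM in Vill and 8.14 ± 8.31 in ff (log2 -3.76, adjusted p = 0.932). Single ff libraries ran from 0.746 to 15.6 CPM of Ggt1 and overlapped those of Vill (0.409 to 0.846). The authors' deposited table calls 4 genes, 2 higher and 2 lower: Gm45774 (10.8), Rn18s-rs5 (0.52), Osr2 (-7.69) and Ggt1 (-3.77).

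Epithelial markers were higher for 10 of 10 members (median log2 0.25, adjusted p = 0.00201, adjusted p = 0.75 with an estimated correlation). Ion and water transport was higher for 19 of 23 (median log2 0.33, adjusted p = 0.000331, adjusted p = 0.63 with an estimated correlation), tight junctions for 15 of 17 with Cldn4 at 1.13 (median log2 0.17, adjusted p = 0.00158, adjusted p = 0.63 with an estimated correlation), and cell division for 20 of 22 (median log2 0.22, adjusted p = 8.75e-06, adjusted p = 0.63 with an estimated correlation). Cholesterol synthesis and uptake (22 of 22, median log2 0.21, adjusted p = 0.000486, adjusted p = 0.63 with an estimated correlation) and the unfolded protein response (17 of 18, median log2 0.22, adjusted p = 0.000806, adjusted p = 0.63 with an estimated correlation) were higher too. Without HFD ff 1 and 3 only tight junctions passed among these, with an adjusted p of 0.801 for ion and water transport, 0.181 for cell division, 0.067 for cholesterol, 0.881 for the unfolded protein response and 0.174 for epithelium.

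Fatty acid oxidation was lower for 19 of 26 members (median log2 -0.14, adjusted p = 0.00287, adjusted p = 0.63 with an estimated correlation), with large differences in Acaa1b, a peroxisomal thiolase (-4.30), Vnn1, a pantetheinase (-3.07), and Pdk4, a pyruvate dehydrogenase kinase (-1.47). Glutathione and xenobiotic metabolism was lower for 18 of 20 (median log2 -0.54, adjusted p = 6.23e-05, adjusted p = 0.63 with an estimated correlation), with the carboxylesterase Ces1g at -4.23 and the glucuronosyltransferase Ugt2b5 at -3.48. Lipid absorption was lower for 12 of 15 (median log2 -0.49, adjusted p = 0.00816, adjusted p = 0.63 with an estimated correlation), Apob among them (-0.97). Without HFD ff 1 and 3 the adjusted p was 0.801 for fatty acid oxidation, 0.801 for glutathione and xenobiotic metabolism and 0.881 for lipid absorption.

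Small intestine genes were lower for 6 of 6 (median log2 -1.53, adjusted p = 0.000138, adjusted p = 0.35 with an estimated correlation), and Slc10a2, the ileal bile acid transporter (-6.16), and Sis, sucrase-isomaltase (-4.91), passed when adjusted over the list alone (adjusted p = 0.0221), against 0 over all genes. The means of this list were 1.66 and 1.94 in HFD ff 1 and 3 and at most 0.08 in the other 6 HFD libraries, and the distal colon position list was at -1.05 and -0.38 in HFD ff 1 and 3 and at 0.54 to 3.81 elsewhere on HFD. Enteroendocrine genes were lower for 9 of 12 (median log2 -0.45, adjusted p = 0.00559, adjusted p = 0.35 with an estimated correlation), with neurotensin (Nts) at -4.95 and the chromogranins Chga at -0.75 and Chgb at -0.67. Adipocyte genes (8 of 8, median log2 -1.04, adjusted p = 0.000223, adjusted p = 0.734 with an estimated correlation) and neuron and glia genes (12 of 13, median log2 -0.67, adjusted p = 0.000367, adjusted p = 0.75 with an estimated correlation) were lower, with the adipokine Cfd at -3.18. Without HFD ff 1 and 3 only 1 cell type list passed on HFD, in a fit that also has fewer ff animals.

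Whether diet alters the effect of epithelial Pcca loss was tested as the HFD difference minus the chow difference. In this design the term also carries sex and age.

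No gene was called with edgeR (0 of 19516), with 496 at an unadjusted p under 0.05 against 976 expected, and DESeq2 and limma-voom called 0 as well. Pcca had a log2 interaction of 0.33 (-0.26 to 0.92, adjusted p = 1). Among the smallest p-values, all with adjusted p = 1, are Gc, the vitamin D binding protein (-6.03), Smim27 (-1.45), Mospd3 (0.51), Rundc3b (-0.82), Trim30c, an interferon-induced ligase (4.29), and the pseudogenes or uncharacterised Glud-ps (2.23), Gm5881 (-4.94), Gm43360 (-2.40) and 3110009E18Rik (-1.77). The largest of these differences rest on few reads. Gc had 5 reads in chow ff and 12 in HFD Vill. In HFD ff and HFD Vill, Gm5881 had 9 and 0 reads and Trim30c 3 and 12. Mt1 stood at -1.39 and Alb at -4.41, with Vil1 at 0.25. With the preset correlation 9 pathway and 10 cell type lists passed, and 0 with an estimated correlation.

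The 200 genes with the smallest chow p, Pcca included, were followed onto HFD, where 122 kept their sign and the fold changes correlated at 0.516 (exact permutation p = 0.0286). Without the chromosome 8 genes within 1 Mb of Gm45774 the correlation over 193 genes was 0.13 (exact permutation p = 0.657), and the rank correlation over all 200 was 0.158 (exact permutation p = 0.4).

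Averaged over both diets, 1 of 19516 genes was called with edgeR, 675 having an unadjusted p under 0.05 against 976 expected. DESeq2 called 6 (Gm45774, Mt1, Mt4, Ciapin1, Cx3cl1, Gm46559) and limma-voom 2. Gm45774 rose by a log2 of 9.68 (SE 0.42, adjusted p = 9.5e-09). Mt1 was next (log2 1.54, SE 0.23, adjusted p = 0.0616), then Mt4 (log2 4.40, adjusted p = 0.119), the chemokine gene Cx3cl1 (log2 -0.38, adjusted p = 0.347) and Ciapin1 (log2 0.44, adjusted p = 0.459), all of which lie within 1 Mb on chromosome 8. Pcca had an average log2 difference of -0.51 (-0.80 to -0.21, adjusted p = 0.962). Phrf1 (0.25), Cpa6 (-1.33), 5830444B04Rik (-0.87), Fam186b (-1.66) and A330076H08Rik (-2.13) share that adjusted p. Cell division was higher for 22 of 22 members (median log2 0.18, adjusted p = 1.77e-05) and tight junctions for 16 of 17 (median log2 0.12, adjusted p = 0.00981), and neither passed with an estimated correlation (adjusted p = 0.702 for both). Neuron and glia markers were lower for 13 of 13 members (median log2 -0.48, adjusted p = 7.23e-05, adjusted p = 0.678 with an estimated correlation), smooth muscle markers for 10 of 10 (median log2 -0.33, adjusted p = 0.00309, adjusted p = 0.678 with an estimated correlation) and small intestine genes for 6 of 6 (median log2 -1.92, adjusted p = 0.00335, adjusted p = 0.583 with an estimated correlation). On chow alone 3 of 4 measured small intestine genes were higher (median log2 0.48, adjusted p = 0.737), and without HFD ff 1 and 3 only cell division and tight junctions passed among the averaged lists named here. Epithelial markers were higher for 10 of 10 (median log2 0.16, adjusted p = 0.00868, adjusted p = 0.678 with an estimated correlation).

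**Figure D4:**
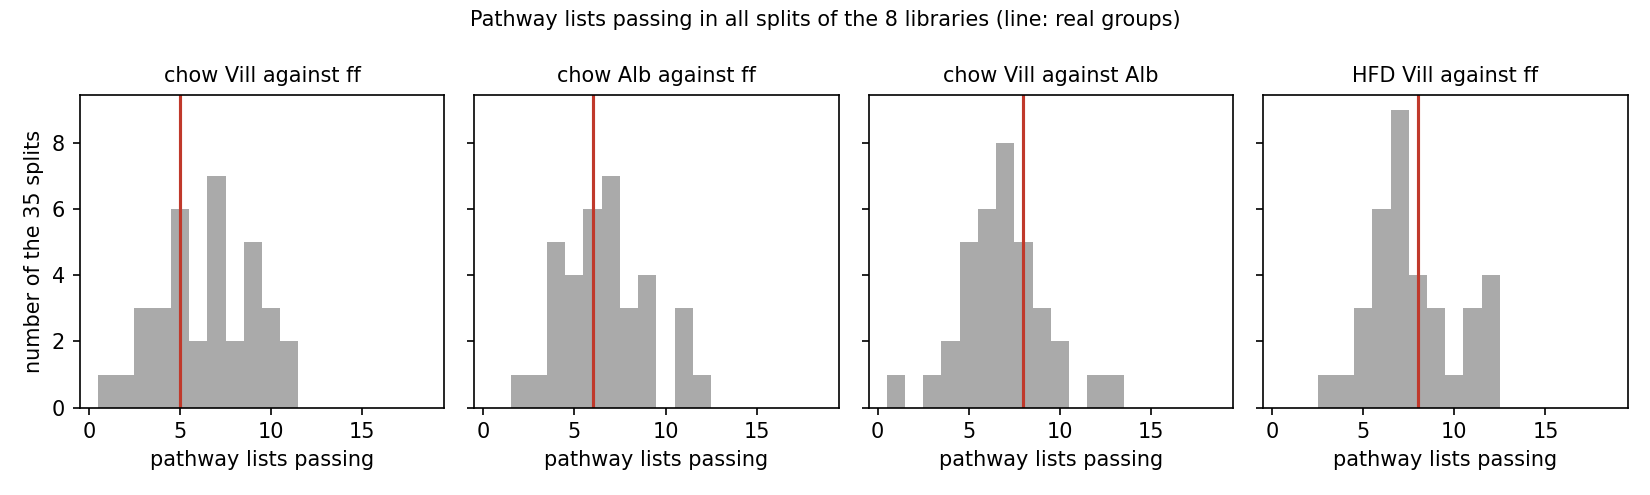
Number of pathway lists passing with the preset correlation in each of the 35 splits of 8 libraries into groups of 4. The line marks the real groups.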

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

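Of the tests in this part, those of a mislabelled library, of reads shared with Mt1, of the chromosome 8 segment, with the position covariate and without HFD ff 1 and 3 were chosen only after the result was seen, and the others were set down before they were run.

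Gm45774 stands higher in Vill colons than in all others, and Mt1 higher in Vill than in ff of the same diet. An exchange of single libraries between Vill and another group is ruled out by the levels of Gm45774, which are blind to an exchange of whole groups or between ff and Alb, since the lowest Vill library has 40.2 CPM of Gm45774 and the highest of the other 12 has 0.398. A fixed share of Mt1 reads wrongly given to Gm45774 is ruled out as well, since the ratio of Gm45774 to Mt1 is 0.0012 in chow Alb and 0.246 in chow Vill. Reads from sequence that only Vill animals carry would escape this test. A count of neighbouring genes neither shows nor excludes an altered segment around the locus. With Gm45774 and the metallothioneins left out, 3 of 40 genes within 1 Mb have a p under 0.05 for the averaged effect. Other windows have a median of 1 and a 95th percentile of 4, and 16.1% of windows hold as many. That count ignores how small the p-values are. Gm45774, Mt1, Mt4, Cx3cl1 and Ciapin1 have the smallest p-values of the averaged effect among all tested genes, and all lie within 1 Mb. The smallest p-values thus gather at this locus, although edgeR called only Gm45774 and their gathering was not itself tested. A metal response might raise Mt1, and Slc30a1, another zinc-induced gene, has an averaged log2 fold change of -0.05 (-0.0528, interval -0.596 to 0.49), which settles nothing.

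The 8 pathway lists of HFD Vill against HFD ff may follow where the samples were taken along the gut. With the distal position score as a covariate 4 of the 8 still pass in the same direction, and 7 lists pass in all. Without HFD ff 1 and 3, the libraries with small intestine genes, 1 of the 8 does, and fatty acid oxidation has an adjusted p of 0.801. Uneven sampling would lower these numbers, and so would the loss of 2 of 4 ff animals in the last fit, so whether Pcca loss contributes stays open. Carry-over of small intestine tissue into these samples and a true proximal position could not be told apart.

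The cholesterol list is lower in chow Alb. The distal position score does not account for it, as the mean log2 fold change is -0.60 (-0.603) with the position covariate and -0.58 (-0.579) without it. That score was close between the groups, at 2.83 ± 2.52 in Alb and 2.98 ± 1.39 in ff. The covariate could therefore hardly move the difference, and sampling differences that the score misses were not tested. The Alb library with squamous genes does not account for it either, the mean being -0.50 (-0.499) without Alb 2. For this list taken alone, 1 of 35 splits, the real one, reaches its p, with the highest other at 23.21 on the -log10 scale. That is the fewest splits possible, and the list stood out as the strongest of its kind. Since 3 of 35 splits have some list as strong, the highest other at 33.71, chance cannot be excluded.

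Chance alone flags about 1 in 20 groups, or 14 of the 275 groups of 4 tested for a single distant library, and 7 were found. HFD Vill 1 has a propionate list mean of 5.35 (others 5.49 to 5.51). HFD Vill 3 has a gluconeogenesis and fructose mean of 2.84 (others 2.45 to 2.49). For tight junctions chow Vill 4 stands at 6.95 (others 6.73 to 6.76) and HFD ff 1 at 6.27 (others 6.5 to 6.53). Chow ff 2 stands out for lipid absorption, at 2.65 (others 1.17 to 1.24), and for enteroendocrine genes, at 4.63 (others 3.46 to 3.62). The T cell mean of chow Alb 2 is -0.387 (others 1.17 to 1.35).

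The Vill effect differed between diets for 9 pathway and 10 cell type lists with the preset correlation and for 0 with an estimated one, and chow and HFD animals differ in sex and age too. As many pathway lists passed in 30 of 100 splits of the libraries, and as many cell type lists in 9. Without HFD ff 1 and 3 most of the lists no longer passed, as given below. Higher on HFD than on chow were the effects on the unfolded protein response (adjusted p = 7.72e-07), cholesterol synthesis (adjusted p = 0.00308), ion and water transport (adjusted p = 0.00542), immediate early genes (adjusted p = 0.0293), antimicrobial defence (adjusted p = 0.0353) and interferon response (adjusted p = 0.047). Lower were those on fatty acid oxidation (adjusted p = 1.37e-06), glutathione metabolism (adjusted p = 0.00308) and lipid absorption (adjusted p = 0.0293). Among cell types the higher ones were fibroblast (adjusted p = 0.00199), goblet cell (adjusted p = 0.00284), endothelium (adjusted p = 0.00294), squamous epithelium (adjusted p = 0.0157), epithelium of all kinds (adjusted p = 0.0263) and B and plasma cell genes (adjusted p = 0.0404). The lower ones were red blood cell (adjusted p = 0.00294), enteroendocrine (adjusted p = 0.0157), T cell (adjusted p = 0.0263) and adipocyte genes (adjusted p = 0.0404).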

How the results depend on the processing

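Of the tests in this part, the fit without HFD ff 1 and 3, the position covariate, the permutation of list means, the carry-over on 200 genes with all its alternatives and everything on the average over diets were chosen only after the result was seen. All others were fixed before the data were examined.

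Gm45774 kept its call in every fit of the contrasts that called it, apart from the chow fits with a block given below. Gene counts moved as follows. Without an expression filter 2 genes were called for chow Vill against ff, Mt1 being added, and 2 for the average over diets. DESeq2 called 4 genes for chow Vill against ff, 4 for Alb against ff, 65 for Vill against Alb, 4 on HFD and 6 for the average. With a surrogate variable 1 gene (Idi1) was called for Alb against ff and 2 for the average. For the average 2 were also called by limma-voom, with the position covariate, and without HFD ff 1 and 3, Mt1 joining each time. Without HFD ff 1 and 3 the HFD comparison called 2, again with Mt1. Leaving out single libraries gave 1 to 2 genes for the average and left the other gene counts as they were.

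With replicate number as a block, 0 genes were called for chow Vill against ff, 0 for chow Vill against Alb and 1 on HFD, and 8 cell type lists passed for chow Vill against Alb. Gm45774 had an adjusted p of 0.053 and 0.0533 in those chow fits. The numbers do not pair animals: correlations between animals of equal number ranged from -0.571 to 0.35 for chow Alb and Vill, -0.463 to 0.472 for Alb and ff, -0.431 to 0.313 for Vill and ff, and -0.395 to 0.446 on HFD.

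With an estimated correlation 0 pathway and 0 cell type lists passed in every comparison. With permutation of list means 0 passed in each comparison of 2 groups, which says little, because the smallest possible p of 0.0286 became 0.542 after adjustment for the cholesterol list in Alb against ff. Without a filter 3 pathway lists passed for chow Vill against ff and 6 cell type lists for the difference between diets. With a surrogate variable 5 cell type lists passed for Alb against ff, 10 for Vill against Alb and 10 on HFD, with 3 pathway lists on HFD. Using only the libraries of the 2 groups, 5 cell type lists passed for Alb against ff. Upper quartile scaling left 4 cell type lists for the average. Without HFD ff 1 and 3, 2 pathway lists and 1 cell type list passed on HFD, and 2 and 4 for the difference between diets.

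Leaving out single libraries moved the pathway lists between 2 and 8 for chow Vill against ff, 4 and 8 for Alb against ff, 4 and 10 for Vill against Alb, 5 and 14 on HFD, 4 and 11 for the difference and 3 and 10 for the average. The cell type lists moved between 5 and 10, 1 and 8, 6 and 9, 5 and 9, 6 and 13, and 4 and 8 in the same order.

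Single lists changed side or lost their call. Without HFD ff 1 and 3 the adjusted p on HFD was 0.801 for fatty acid oxidation, 0.067 for cholesterol, 0.881 for lipid absorption and 0.801 for glutathione metabolism. In that fit the difference between diets had 0.374 for cholesterol, 0.391 for B and plasma cells and 0.391 for T cells, and the average had 0.301 for cholesterol and 0.765 for glutathione metabolism. With a surrogate variable neurons and glia on HFD had 0.954, and B and plasma cells for the difference 0.63. Without single libraries the adjusted p of the interferon list ranged from 5.65e-11 to 0.84 for Alb against ff and from 3.94e-07 to 0.988 for the difference, and that of T cells for the difference from 2.1e-06 to 0.71. The propionate list for chow Vill against ff lost its call without any of 6 of the 8 libraries (0.00298 to 0.261), and B and plasma cells for Alb against ff without any of 4 (5.97e-07 to 0.248). Many other lists lost theirs without at least 1 library.

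Pcca kept its sign in chow Vill under every choice. For the difference between diets it was -0.04 (-0.0409) without HFD ff 1 and 3, and without single libraries it ranged from -0.217 to 0.0227 for Alb against ff. Genes that were not called changed sign: Vil1 on chow was 0.0138 with a surrogate variable and ranged from -0.186 to 0.201 without single libraries (-0.305 to 0.0419 for Alb against ff), and the albumin gene on HFD, at -0.73 at first, was 0.0576 by limma-voom and ranged from -1.14 to 0.0946.

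The carry-over was 0.158 by ranks, 0.13 without genes near Gm45774, and 0.442 to 0.548 without single libraries, with an exact permutation p of 0.0571 when HFD Vill 1, 2 or 4 was left out. With the ff animals divided between the chow contrasts, the correlation of the Vill and Alb fold changes was -0.379, -0.0938, -0.22, -0.346, -0.179 and -0.187.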

Other observations

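Of the tests in this part, that of the liver genes and the splits for the average over diets were chosen only after the result was seen, and the other splits of the libraries were planned.

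Each comparison was repeated with the same libraries divided into other groups. For chow Vill against ff the real split called 1 gene, with 1 of 35 splits as high and the highest other at 0. The gene is Gm45774, whose high and low animals any other split mixes, so this adds nothing to its separation of the groups. Chance cannot be excluded for the 5 pathway lists (27 of 35, highest other 11) or 8 cell type lists (16 of 35, highest other 12). For Alb against ff the count of 0 genes decides nothing, as every split reaches it (35 of 35), and chance cannot be excluded for 6 pathway lists (24, highest other 12) or 3 cell type lists (30, highest other 13). For Vill against Alb it cannot be excluded for 1 gene (2 of 35, highest other 1155), 8 pathway lists (12, highest other 13) or 5 cell type lists (30, highest other 11). On HFD it cannot be excluded for 1 gene (4 of 35, highest other 246), 8 pathway lists (15, highest other 12) or 5 cell type lists (29, highest other 11). For the difference between diets the count of 0 genes again decides nothing (100 of 100, highest other 2523), and chance cannot be excluded for 9 pathway lists (30, highest other 12) or 10 cell type lists (9, highest other 12). For the average it cannot be excluded for 1 gene (5 of 100, highest other 93), 6 pathway lists (65, highest other 13) or 7 cell type lists (47, highest other 15).

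These counts take no notice of which gene is called or how far it moves, and Gm45774 separates Vill from all other libraries on both diets. Splits that call many more genes than the real one point to structure of the samples that is unrelated to genotype. Among comparisons of 2 groups, the largest on chow sets Alb 1 and 3 with Vill 1 and 4 against the rest (1155 genes), and on HFD ff 1 and 3 with Vill 1 and 2 (246 genes). Leaving out the real split, a median of 7 pathway lists passed per split in each comparison, so the preset correlation of 0.01 lets through lists at about the rate of the real groups.

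All 10 of 10 liver genes have a higher mean in chow Vill than in chow ff. Mean CPM were 19.7 against 1.54 for Alb, 1.54 against 0.148 for Ahsg, 0.586 against 0.0368 for Fga, 0.614 against 0.0892 for Fgb, and 0.199 against 0.0145 for Serpina1c. Some of the others, such as Trf (43.6 against 39.4) and Ttr (19.1 against 13.7), are also expressed in colon. The albumin reads lie mainly in chow Vill 1 (26 CPM) and chow Vill 4 (47.5 CPM), which are on the same side of the split with 1155 genes. Albumin does not follow that split in Alb animals. Alb 1 and 3, on the side of Vill 1 and 4, have 2.28 and 8.21 CPM, and Alb 2 and 4 have 6.11 and 2.39. Within their group, chow Vill 1 and 4 also hold the highest Ahsg, Fga, Fgb, Serpina1c, Apoa2 and Apoh. Trf, Ttr and Cps1 are instead highest in chow Vill 3.

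The series holds no animals with Villin-Cre and without floxed Pcca. Gm45774 has 40.2 CPM or more in Vill libraries and is near absent in Alb colons, which carry another Cre line and a Pcca level near that of ff. Loss of Pcca in the epithelium could raise it, and so could the Villin-Cre transgene itself, through its place of insertion or through sequence it carries. The 3 of 40 neighbouring genes with a p under 0.05 do not separate these explanations. The smallest p-values of the averaged effect gather within 1 Mb of Gm45774 on chromosome 8, while Pcca lies on another chromosome. Cx3cl1 (log2 -0.52 on chow, -0.26 on HFD) and Ciapin1 (0.46 and 0.41) kept their sign, though edgeR called neither. An insertion near the locus would give such a pattern, and a response to Pcca loss need not. Only animals with the transgene alone, or the reads at the locus, would decide.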
